A study of Mus musculus with 16 samples.

How the data were processed

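Gene expression was measured in 16 samples of Ba/F3 cells, a murine pro-B cell line that needs interleukin 3 to grow, on Affymetrix MTA-1 mouse arrays. Per the labels, the cells were plated in medium with interleukin 3, doxycycline was given at 80 ug per ml where it was given, and 150 ng of total RNA entered the labelling of each array. One set of cells had been transduced with a retroviral Tet-On construct that carries the murine Sox11 coding sequence, so that doxycycline switches the construct on. The groups were transduced cells with doxycycline (Sox11-ON), transduced cells without it (Sox11-OFF), non-transduced cells with doxycycline (NT-ON) and non-transduced cells without it (NT-OFF), with 4 arrays each. The labels do not say whether the 4 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which can be technical.

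The deposited values are log2 signals, 1 per probe set and array. They were made with RMA, and Affymetrix Expression Console 1.4 was used, per the submitters' processing notes. The labels of the transduced samples name the mouse genome version mm10. Whether the arrays of transduced and non-transduced cells were hybridised and normalized together is not given in the sources used here, and the values do not settle it. A difference between transduced and non-transduced cells therefore cannot be told apart from a difference between runs, while such a constant difference cancels in the comparison of both doxycycline effects. The number of arrays limits the precision of every value. On each array, the median of the positive control probe sets lay 4.75 to 5.06 log2 units above that of the negative controls.

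The table held 725678 rows, of which 437027 were exon regions, 282044 were exon junctions and 6607 were control probe sets. Control rows made up 0.91% of the table and entered no test. In the platform's annotation, 580167 of the other rows had 1 gene symbol, 18694 had several and 120210 had none. Gene symbols were taken only from rows with 1 symbol. The value of a gene on an array was the median over its exon regions, and junctions were left out. This gave 31366 genes from 338822 exon regions, with a median of 6 regions per gene and 7644 genes that had 1 region. Of these gene symbols, 29748 were also symbols of the reference annotation of the GRCm38 assembly, from which coordinates were taken. No expression filter was applied. No pair of arrays held the same values, and the most similar pair had a Pearson correlation of 0.998 across genes.

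All 16 arrays entered a single limma fit with a mean for each of the 4 groups and no covariate, which left 12 residual degrees of freedom and 4.47 prior degrees of freedom. The 5 comparisons were contrasts of that fit: Sox11-ON against Sox11-OFF, NT-ON against NT-OFF, the difference between those doxycycline effects, Sox11-OFF against NT-OFF, and Sox11-ON against NT-ON. Moderated tests came from eBayes, were two-sided, and were adjusted by the Benjamini-Hochberg method over the 31366 genes. A gene was called changed at an adjusted p under 0.05, and every adjusted p of a gene given here is from limma. Log2 changes are given with the standard error (SE) of the fit, and group levels as mean and standard deviation (SD) over 4 arrays. Single exon regions of Sox11 were tested in the same model fitted to all rows.

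Before the data were examined, 35 gene lists were fixed for pro-B cells, interleukin 3 dependence, adhesion, growth, stress and doxycycline, together with markers of other blood cells. They held 877 genes, of which 824 were measured, 4 of them under an older symbol. Lists with at least 5 measured members were tested against all other genes with limma's camera at a preset correlation of 0.01, and adjusted over the lists within a comparison. The test was repeated with the correlation between genes estimated from the data. The genes named in the text were fixed by a rule set at the same time. For Sox11-ON against Sox11-OFF and for the difference of effects, the rule took the 10 genes with the largest positive and the 10 with the largest negative change. For the other comparisons it took 5 and 5. Such a gene had to pass the threshold with no overlap between its groups, and predicted genes, small RNAs and olfactory and vomeronasal receptors were left out. The rule also took Sox11 and up to 4 members of each list with the smallest adjusted p under 0.05. Other list members are named to describe a list, and were chosen after their values were seen.

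The alternatives set beforehand were a fit on the arrays of the comparison only, eBayes with trend and robust moderation, leaving out dim genes, the mean over exon regions, each row by itself, quantile normalization, median centring of each array, array weights, an added threshold of 2-fold, the replicate number as a block, and leaving out each array in turn. For the lists they were the estimated correlation, fry, no dim genes, the block and both scalings. The control probe distance of each array as a covariate, leaving out each array for the list tests, and the same settings for the overlap were added after the data had been seen.

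The fit was tested on simulated data made from the means and residual spreads of the 31366 genes, with 100 genes changed by 0.5 and 100 by 1 in each comparison. For Sox11-ON against Sox11-OFF, it recovered 97% of the changes of size 1 and 80% of those of size 0.5 on the log2 scale, and called 8 of 31141 unchanged genes. For NT-ON against NT-OFF the shares were 98% and 81%, and for the difference of effects 98% and 33%. For Sox11-OFF against NT-OFF they were 98% and 74%, and for Sox11-ON against NT-ON 99% and 69%. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.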

Results

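Genome-wide expression was compared in Ba/F3 pro-B cells with and without induction of a Sox11 transgene. Sox11 encodes a transcription factor of the SoxC group that is expressed in the developing nervous system and in most mantle cell lymphomas. The design sets doxycycline in transduced cells (Sox11-ON against Sox11-OFF, 4 arrays each) beside doxycycline in non-transduced cells (NT-ON against NT-OFF, 4 arrays each). The title of the series names cell aggregation and growth suppression as the processes of interest. Median values over all rows of the table lay between 6.16 and 6.21 log2 units on the 16 arrays.

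Sox11 itself lies on mouse chromosome 12 at 27334268 to 27342718 (GRCm38) and had 15 exon regions on the array. A single region, PSR1200010816, followed the labels. Its level was 11.35 ± 0.06 in Sox11-ON, 8.84 ± 0.20 in Sox11-OFF, 7.46 ± 0.24 in NT-ON and 7.46 ± 0.08 in NT-OFF (mean ± SD, n = 4). With doxycycline it rose 5.67-fold in transduced cells (log2 change 2.50, SE 0.12, adjusted p = 2.82e-09) and not in non-transduced cells (log2 change 0.00, SE 0.12, adjusted p = 0.999). The difference between both doxycycline effects was 2.50 (SE 0.16, adjusted p = 7.14e-07). Without doxycycline the region was higher in transduced than in non-transduced cells, by 1.38 (SE 0.12, adjusted p = 1.16e-04). The other 14 regions did not pass in Sox11-ON against Sox11-OFF, and the median over all 15 regions changed by 0.04 (SE 0.10, adjusted p = 0.857), while their mean changed by 0.13 and passed (adjusted p = 0.0184). The positions of the regions within the transcript are not given in the sources used here, so which of them lie in the coding sequence carried by the construct was not determined.

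**Figure D1:**
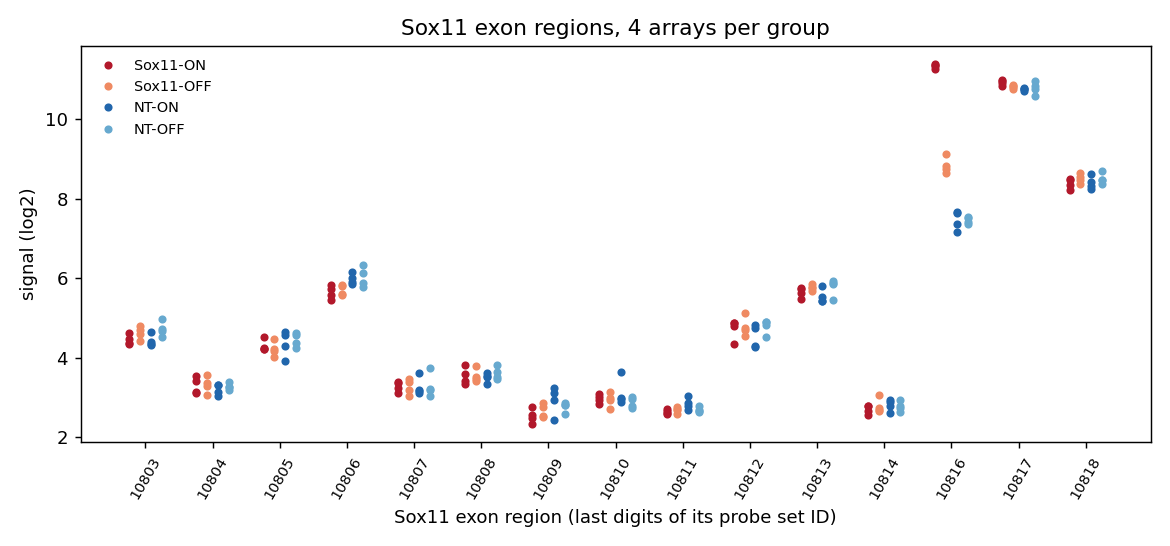
Signal (log2, vertical axis) of the 15 Sox11 exon regions (horizontal axis), with a point for each of the 4 arrays of each group. PSR1200010816 separates Sox11-ON, with a mean of 11.35, from Sox11-OFF, with 8.84, and from both non-transduced groups, with 7.46 each.

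With induction of the construct (Sox11-ON against Sox11-OFF), single genes known from neutrophils were among those that rose most, and single genes known from macrophages among those that fell most, while the list of myeloid genes did not pass (adjusted p = 0.105). The largest rise was that of Mmp8, which encodes neutrophil collagenase (chromosome 9, 7558429 to 7568486). It went from 5.02 ± 0.27 in Sox11-OFF to 9.25 ± 0.11 in Sox11-ON (mean ± SD, n = 4), an 18.9-fold increase (log2 change 4.24, SE 0.14, adjusted p = 3.37e-12). S100a9 and S100a8, the subunits of calprotectin, rose by 2.47 (SE 0.12) and 2.46 (SE 0.14), Gbp9, a guanylate-binding protein gene, by 2.40 (SE 0.10), and Stfa1, a stefin, by 2.35 (SE 0.14). Among the 10 largest rises were also Zc4h2 (2.35), Tdrd12 (2.35), Gsta4 (2.34, a glutathione S-transferase), Glyat (2.34) and Far2 (2.31). C3ar1, the receptor of the complement fragment C3a (chromosome 6, 122847140 to 122856157), fell most, from 10.29 ± 0.10 to 7.25 ± 0.10, which is an 8.25-fold decrease (log2 change -3.04, SE 0.06, adjusted p = 1.15e-14). Serpinb1a, an inhibitor of neutrophil proteases, fell by 2.55 (SE 0.08) and the chemokine gene Ccl3 fell by 2.26 (SE 0.07). The other large decreases were those of Ndrg1 (-2.00), Ero1l (-1.96), Cd68 (-1.90), Tmem71 (-1.85), Tarm1 (-1.82), Hmox1 (-1.81, heme oxygenase 1) and Sat1 (-1.72). As the naming rule demands, the 4 arrays of one group lay above the 4 of the other for each of these 20 genes. Of the 10 that rose, Gsta4 alone lay above the 95th percentile of the negative control probe sets, 7.30, in Sox11-OFF, and S100a8, Glyat and Tdrd12 lay below their median, 4.35; C3ar1 and Tmem71 lay below 7.30 in Sox11-ON. Background can compress the fold changes of these genes, those of Mmp8 and S100a9 included.

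**Figure D2:**
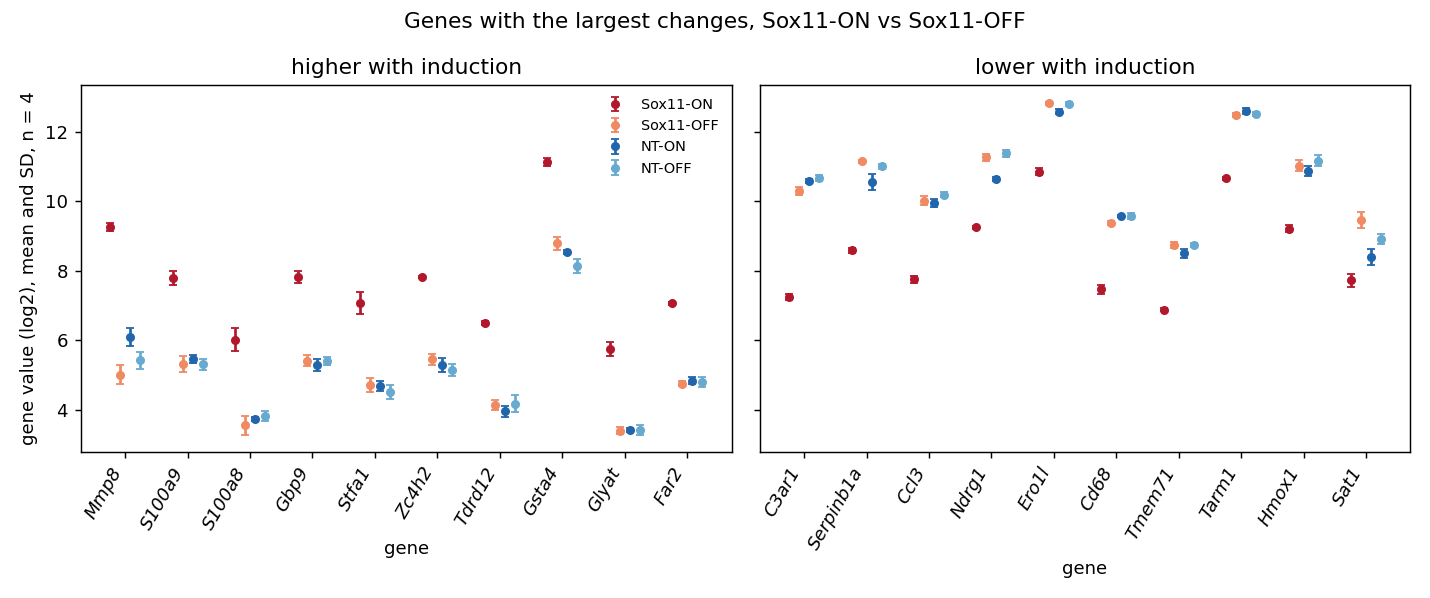
Gene values (log2, mean and SD over 4 arrays per group) of the 10 genes with the largest rises (left) and the 10 with the largest decreases (right) in Sox11-ON against Sox11-OFF. Mmp8 reached 9.25 in Sox11-ON against 5.02 in Sox11-OFF, and C3ar1 lay at 7.25 in Sox11-ON against 10.29 in Sox11-OFF, with NT-ON at 10.58 and NT-OFF at 10.67.

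In all, 7863 of the 31366 genes changed with induction, 4068 higher and 3795 lower. Most changes were small: the median absolute log2 change of the genes called was 0.34, and 261 genes changed at least 2-fold (168 higher, 93 lower). The groups did not overlap for 28.1% of genes, where chance gives 2.86%.

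Genes of DNA replication and entry into S phase rose as a group. Of 32 measured G1/S genes, 31 were higher and none lower (32 and 0 when adjusted over the list alone), with a median log2 change of 0.74 (camera adjusted p = 1.74e-28). The list held its call with an estimated correlation (adjusted p = 0.0316). Examples are Mcm7, a subunit of the replicative helicase (1.36, SE 0.10), Gins1 (1.35, SE 0.08), Rfc3, a clamp loader subunit (1.27, SE 0.09), and Pole, the catalytic subunit of DNA polymerase epsilon (0.78, SE 0.06). Cdk4, the kinase partner of the D cyclins, was higher by 0.86 (SE 0.06). The D cyclin and CDK list had 3 of 5 members higher (adjusted p = 0.0138), without holding its call with an estimated correlation (adjusted p = 0.211). One of the 3 was Ccnd3 (0.62, SE 0.09), whose change was -0.010 when exon regions were averaged instead of taking their median. G2/M genes did not move one way: 5 of 33 were higher and 12 lower (5 and 12 when adjusted over the list alone), and the list did not pass (adjusted p = 0.166). Bub1, of the spindle checkpoint, and Prc1, of the midzone, each fell by 0.65, while Kif20a was higher by 0.55. Of 22 cell cycle inhibitors, 10 were lower and 1 was higher (11 and 3 when adjusted over the list alone, camera adjusted p = 0.00677), and the call was lost with an estimated correlation (adjusted p = 0.0904). Tob1 fell by 0.60 and Rbl2 fell by 0.39, and Rbl1 was higher by 0.44.

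Glycolysis and hypoxia genes, the unfolded protein response and lysosomal genes fell. Of 31 measured glycolysis and hypoxia genes, 22 were lower and 1 was higher (24 and 1 when adjusted over the list alone), with a median of -0.43 (adjusted p = 2.02e-15, and 0.0244 with an estimated correlation). Beside Ndrg1 and Ero1l, the glucose transporter gene Slc2a1 fell by 1.26 (SE 0.07) and the prolyl hydroxylase gene P4ha1 fell by 1.09 (SE 0.06). In the unfolded protein response list, 15 of 21 members were lower and 0 higher (16 and 0 when adjusted over the list alone), with a median of -0.43 (adjusted p = 4.81e-11, and 0.0197 with an estimated correlation). Dnajb9 fell by 1.06 (SE 0.07), Herpud1 fell by 0.78 (SE 0.07), and Hspa5, the chaperone BiP, fell by 0.73 (SE 0.05). Of 24 autophagy and lysosome genes, 15 were lower and 2 higher (16 and 2 when adjusted over the list alone, adjusted p = 5.04e-06, and 0.0471 with an estimated correlation). Lamp1 fell by 0.72, the autophagy receptor gene Sqstm1 fell by 0.69, and Ulk1, a kinase that starts autophagy, was higher by 0.64. In the plasma cell list 3 of 12 members were lower and 0 higher, among them Xbp1 (-0.57) and Edem1 (-0.65), and its call (adjusted p = 0.0148) was lost with an estimated correlation (adjusted p = 0.170).

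**Figure D3:**
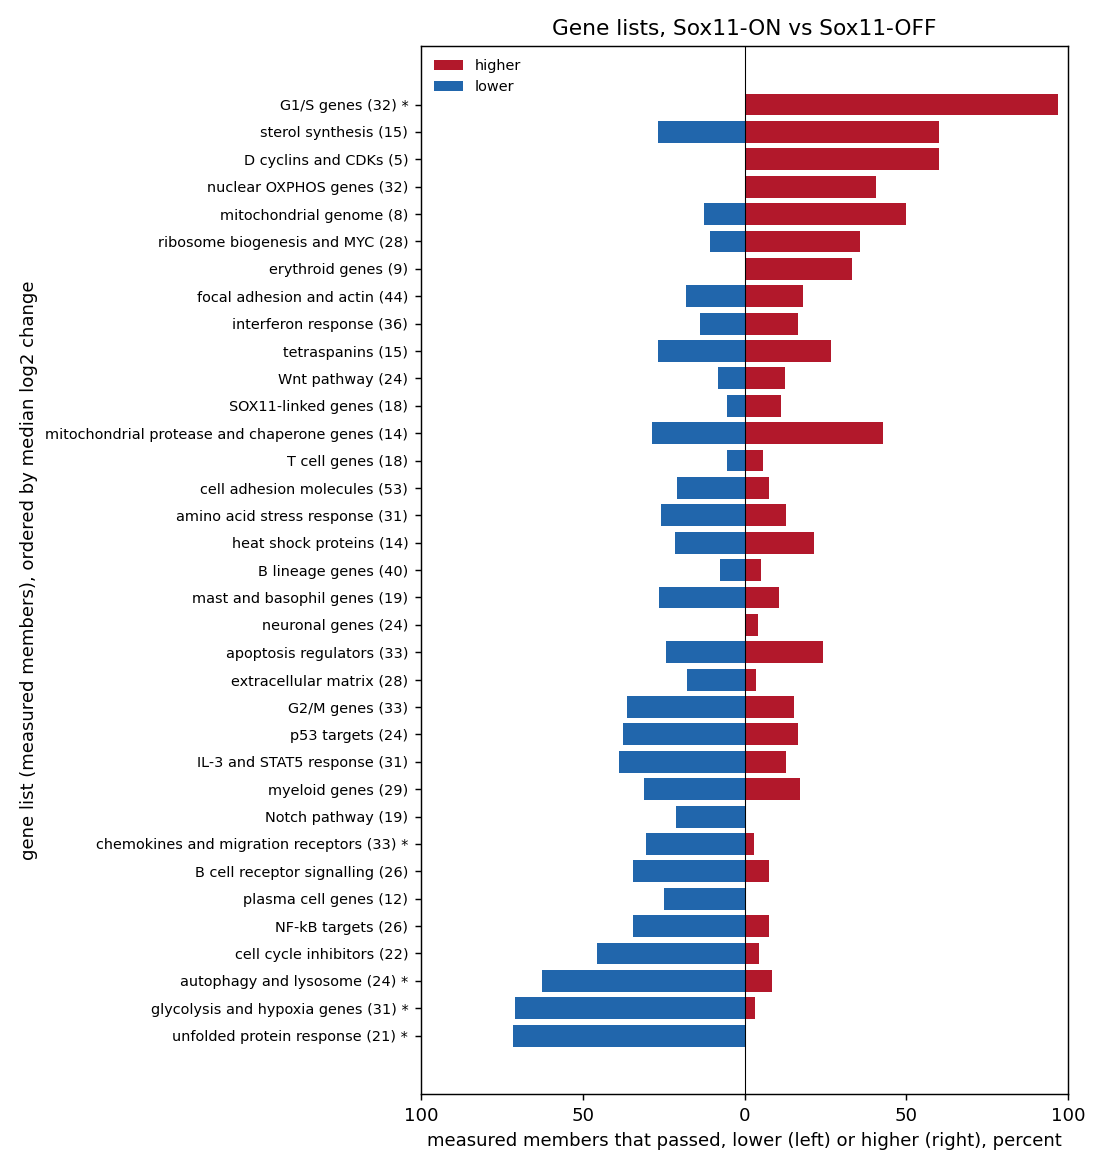
Share of the measured members of each of the 35 gene lists that were higher (right) or lower (left) in Sox11-ON against Sox11-OFF (horizontal axis, percent), ordered by the median log2 change of the list, with the number of measured members in brackets. An asterisk marks the 5 lists whose camera call held with an estimated correlation; the G1/S list has 31 of 32 members on the right, and the unfolded protein response 15 of 21 on the left.

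Chemokine and migration receptor genes also fell, with 10 of 33 lower and 1 higher (10 and 1 when adjusted over the list alone, adjusted p = 0.00134, and 0.0197 with an estimated correlation). Beside Ccl3, these included Gpr183, an oxysterol receptor that guides B cell migration (-1.24, SE 0.05), and Ccl5 (-0.85, SE 0.07). Adhesion molecules did not pass as a group (4 of 53 higher, 11 lower, the same numbers when adjusted over the list alone, adjusted p = 0.0804). Single members changed in both directions. Itgam, the integrin alpha M subunit, was 2.65-fold lower, Selplg, the P-selectin ligand, fell by 0.84 (SE 0.05) and Itgb7 fell by 0.78 (SE 0.05), whereas Itga2 was higher by 0.98 (SE 0.07). In the focal adhesion and actin list, 8 of 44 members were higher and 8 lower (9 and 8 when adjusted over the list alone, adjusted p = 0.790). Flna, which encodes the actin crosslinker filamin A, was higher by 1.23 (SE 0.05), and Ptk2b, a focal adhesion kinase, fell by 0.85 (SE 0.07). Of 15 tetraspanins 4 were higher and 4 lower (adjusted p = 0.922), with Cd53 at -0.64 and Cd151 at 0.74. Of 28 extracellular matrix genes 1 was higher, the protease gene Mmp9 (0.85), and 5 lower, among them Lama5 (-0.61), without a call for the list (adjusted p = 0.101). Mmp9 lay at 6.29 in Sox11-OFF, below the 95th percentile of the negative controls, 7.30.

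The B lineage list held 40 measured genes, of which 2 were higher and 3 lower, and it did not pass (adjusted p = 0.553). Tcf3, which encodes the E2A transcription factor, was higher by 0.84 (SE 0.05), while Cd74, the invariant chain, fell by 0.93 (SE 0.08) and Ptprc, which encodes CD45, fell by 0.70 (SE 0.05). B cell receptor signalling genes had 9 of 26 members lower and 2 higher (10 and 2 when adjusted over the list alone, adjusted p = 0.0176, and 0.170 with an estimated correlation), with the phosphatase genes Ptpn6 (-0.85) and Inpp5d (-0.59) among those lower. The interleukin 3 and STAT5 list had 12 of 31 members lower and 4 higher (adjusted p = 0.0265, and 0.211 with an estimated correlation). Il2ra fell by 1.23 and the kinase gene Pim2 fell by 1.06, whereas Gzmb was higher by 1.18 and Dusp6, a phosphatase that acts on ERK, by 1.09. Among 33 apoptosis regulators, 8 were higher and 8 lower (adjusted p = 0.842). Fas, the death receptor, fell by 1.56 (SE 0.07), Casp4 fell by 1.51 (SE 0.08) and Casp6 was higher by 0.78 (SE 0.06). The p53 target list, with 4 of 24 members higher and 9 lower, did not pass (adjusted p = 0.0890).

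Markers of other blood cells moved in both directions. Of 29 measured myeloid genes, 5 were higher and 9 lower (5 and 12 when adjusted over the list alone, adjusted p = 0.105). Beside S100a8 and S100a9, Mpo, myeloperoxidase, was higher by 2.31 and Ltf, lactotransferrin, by 1.74. Their levels in Sox11-OFF, 6.18 and 5.90, lay below the 95th percentile of the negative controls, 7.30, so background limits these values. Beside Cd68, Emr1, the F4/80 antigen of macrophages, fell by 1.72. Itgam (-1.40) and Ncf1, a subunit of the phagocyte oxidase (-1.35), which neutrophils and macrophages both express, were lower too, so the genes do not part by cell type. Of 19 mast cell and basophil genes 2 were higher and 5 lower (adjusted p = 0.231), with Cma1 at -1.36 and Cpa3 at 0.78. Of 9 erythroid genes 3 were higher and 0 lower, Nfe2 most (0.80), and the call of the list (adjusted p = 0.0239) was lost with an estimated correlation (adjusted p = 0.0904). NF-kB targets had 9 of 26 members lower and 2 higher (adjusted p = 0.00696, and 0.0904 with an estimated correlation), with Ccl3 (-2.26) and Ccl5 (-0.85) among the lower ones and Tnf (0.97) and Nfkb1 (0.55) higher. Of 36 interferon response genes 6 were higher, Usp18 (1.45) and Ifit2 (1.46) among them, and 5 lower, Tap1 (-0.67) among them, without a call for the list (adjusted p = 0.842).

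A list of 18 genes linked to SOX11 in lymphoma and neural cells had 2 members higher and 1 lower and did not pass (adjusted p = 0.842). Mex3a, an RNA-binding protein gene, was higher by 1.94 (SE 0.17), Msi2 was higher by 0.16 (SE 0.05) and Cxcr4 fell by 0.30 (SE 0.06). Pax5 and Prdm1 did not pass. Of 24 neuronal genes 1 was higher, Stmn1, which encodes the microtubule regulator stathmin (1.74, SE 0.07), and 0 were lower. Nuclear genes of oxidative phosphorylation had 13 of 32 members higher and 0 lower (adjusted p = 0.00160), among them Cycs (0.54). Ribosome biogenesis and MYC genes had 10 of 28 higher and 3 lower (adjusted p = 0.0138), among them Odc1 (0.87). Neither held its call with an estimated correlation (adjusted p = 0.375 and 0.451). The remaining lists did not pass. Among T cell genes 1 of 18 was higher and 1 lower (adjusted p = 0.842), among amino acid stress response genes 4 of 31 were higher and 8 lower (0.0872), and among mitochondrially encoded genes 4 of 8 were higher and 1 lower (0.105). Mitochondrial proteases and chaperones had 6 of 14 members higher and 4 lower (0.842), sterol synthesis 9 of 15 higher and 4 lower (0.0919), and heat shock proteins 3 of 14 higher and 3 lower (0.991). Wnt pathway genes had 3 of 24 members higher and 2 lower (0.842), and Notch pathway genes 0 of 19 higher and 4 lower (0.0949), each value in brackets being the adjusted p. In the SOX11-linked, neuronal, tetraspanin and Wnt lists the median and the mean change differed in sign. None of the 14 list calls turned direction under quantile normalization or median centring.

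Doxycycline in non-transduced cells (NT-ON against NT-OFF), the background of the system, changed 92 genes, 53 higher and 39 lower, and 0 by 2-fold or more. The largest decreases were those of Ankrd37, which fell by 0.87 (SE 0.11, adjusted p = 0.00227), and Ndrg1, which fell by 0.73 (SE 0.06, adjusted p = 5.08e-05), both of the glycolysis and hypoxia list. Ccng2 (-0.68), Sap30 (-0.64) and Fxyd4 (-0.61) were the other large decreases. The largest rises under the naming rule were those of Zmat1 (0.65), Slc7a11, the cystine transporter gene (0.59, SE 0.07), Depdc7 (0.59), Rad51c (0.48) and Gpt2 (0.48). Mmp8, which the rule did not take here, was higher by 0.67, at 6.10 in NT-ON and 5.43 in NT-OFF. Of 31 glycolysis and hypoxia genes 3 were lower and 0 higher (13 and 0 when adjusted over the list alone, median -0.11, adjusted p = 2.11e-10, and 0.124 with an estimated correlation). Of 31 amino acid stress response genes 7 were higher and 0 lower (10 higher and 3 lower when adjusted over the list alone, median 0.04, adjusted p = 4.80e-04, and 0.124 with an estimated correlation), among them Aldh18a1 (0.39), Pck2 (0.40) and Asns (0.36). The mitochondrial genome list had 2 of 8 members higher, ND3 (0.32) and COX2 (0.29), with a median of 0.12 and an adjusted p of 4.80e-04 (0.323 with an estimated correlation). G1/S genes (median 0.10, adjusted p = 4.80e-04), ribosome biogenesis and MYC genes (0.06, 0.00485), G2/M genes (0.07, 0.00524), interferon response genes (0.08, 0.0126), D cyclins and CDKs (0.14, 0.0162), NF-kB targets (-0.09, 0.0162) and sterol synthesis genes (-0.09, 0.0400) passed as lists, although among their members only 1 NF-kB target was called. Of these lists D cyclins and CDKs, NF-kB targets, and ribosome biogenesis and MYC genes moved the same way with induction and did not pass for the difference of effects (adjusted p = 0.184, 0.0987 and 0.240), while G1/S genes did (1.57e-25). In all 10 lists passed, and none held its call with an estimated correlation. In limma 3991 genes had an unadjusted p under 0.05, and the count of 92 moved both ways with the settings. It was 249 with trend and robust moderation, 323 without dim genes and 315 with the mean over exon regions, but 38 with median centring, 16 with the control distance as a covariate and 4 when only the 8 arrays of this comparison were fitted. Leaving out single arrays moved the count to 27 without NT-ON replicate 2, 28 without NT-ON replicate 3, 35 without NT-OFF replicate 4, 37 without NT-OFF replicate 3, 44 without NT-ON replicate 4 and 52 without NT-ON replicate 1. The balance of higher and lower genes did not hold either, with 18 higher and 26 lower without NT-ON replicate 4, 15 and 22 without NT-OFF replicate 3, 14 and 21 without NT-OFF replicate 4, and 13 and 14 without NT-ON replicate 2.

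The effect of induction was then set against the effect of doxycycline alone. Of the 53 genes higher in NT-ON, 22 were also higher in Sox11-ON, where 6.87 would be shared by independent lists, and 9 were lower. Of the 39 genes lower in NT-ON, 26 were also lower in Sox11-ON, where 4.72 would be, and 5 were higher. These comparisons share no array, but both come from the single fit and share the spread estimate of each gene. The expected numbers count all 31366 genes, those at background included. The excess over them was therefore not tested. The shared count of 48 fell to 16 without NT-ON replicate 2 or 3, 22 without NT-OFF replicate 3, 24 without NT-OFF replicate 4, 29 without NT-ON replicate 4 and 30 without NT-ON replicate 1, to 22 with median centring, 9 with the covariate and 4 when only the 8 arrays of each comparison were fitted. It was 155 with trend and robust moderation, 199 without dim genes and 187 with the mean over exon regions. Ndrg1 was in the shared set, with a decrease of 0.73 in non-transduced and 2.00 in transduced cells. Among the 261 genes that changed at least 2-fold with induction, 13 were also called in non-transduced cells, each in the same direction. The median absolute log2 change of these 261 genes was 1.22 with induction and 0.12 in non-transduced cells. Because the genes were chosen by their change with induction, that choice sets this contrast in part.

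**Figure D4:**
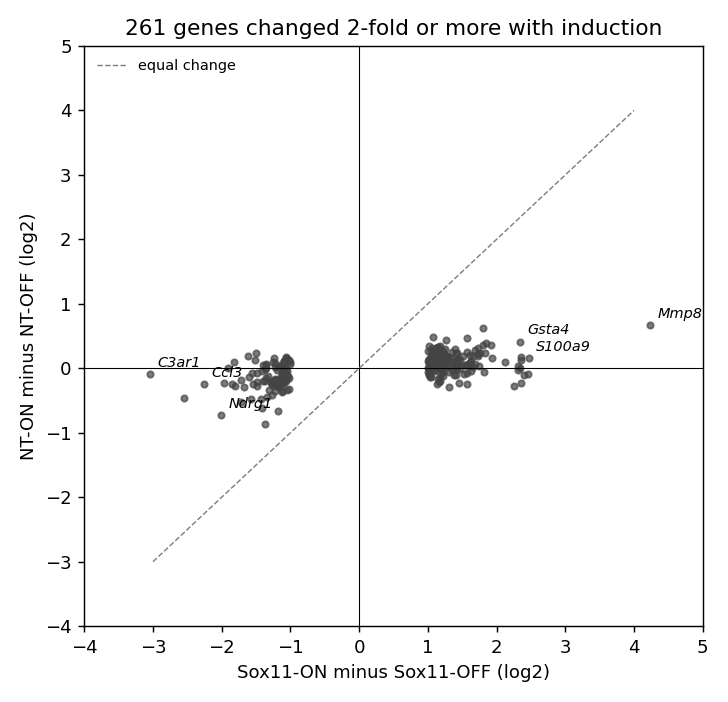
Log2 change with doxycycline in non-transduced cells (vertical axis) against that in transduced cells (horizontal axis) for the 261 genes that changed at least 2-fold with induction, with a dashed line where both would be equal. Values on the vertical axis lie between -0.87 and 0.67, while those on the horizontal axis reach 4.24 for Mmp8 and -3.04 for C3ar1. The value of 0.67 is also that of Mmp8, at 6.10 in NT-ON and 5.43 in NT-OFF. The genes were chosen by their change on the horizontal axis.

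The difference between both doxycycline effects tests which changes go beyond doxycycline alone, and a constant difference between transduced and non-transduced arrays cancels in it. It passed for 4821 genes, 2475 of them higher and 2346 lower, and for 210 by 2-fold or more. Of the 7863 genes called with induction, 4454 (56.6%) were also called here with the same sign, as were 260 of the 261 that changed at least 2-fold. The difference includes the arrays of the induction comparison. The largest positive differences were those of Mmp8 (3.57, SE 0.20), Tdrd12 (2.58), S100a8 (2.54), Thsd1 (2.52), Gbp9 (2.51), Glyat (2.33), Mpo (2.33), S100a9 (2.31), Far2 (2.27) and Zc4h2 (2.22). All 10 lay below 7.30, the 95th percentile of the negative controls, in Sox11-OFF, NT-ON and NT-OFF, and Tdrd12, S100a8 and Glyat below the median of 4.35, so background limits these values and their order. The largest negative ones were those of C3ar1 (-2.96, SE 0.09), Serpinb1a (-2.09), Ccl3 (-2.02), Tarm1 (-1.92), Cd68 (-1.90), Tmem154 (-1.82), Gapt (-1.74), Ero1l (-1.73), Casp4 (-1.63) and Tmem71 (-1.61). Of 16 lists past the threshold, 7 held their call with an estimated correlation. G1/S genes had 27 of 32 members higher and 0 lower (median 0.65, adjusted p = 1.57e-25, and 0.0376 with an estimated correlation), and Rrm2, a subunit of ribonucleotide reductase, differed by 1.00 (SE 0.10). The unfolded protein response had 14 of 21 members lower (adjusted p = 1.85e-11, and 0.0328), glycolysis and hypoxia genes 17 of 31 (adjusted p = 1.85e-11, and 0.0376), autophagy and lysosome genes 13 of 24 with 2 higher (adjusted p = 8.09e-06, and 0.0376), and chemokines and migration receptors 6 of 33 (adjusted p = 0.00358, and 0.0369), where the second value is the adjusted p with an estimated correlation. Amino acid stress response genes had 11 of 31 members lower and 0 higher (adjusted p = 3.80e-04, and 0.0376 with an estimated correlation). Several of these moved in opposite directions with doxycycline: Pck2 was higher by 0.40 in non-transduced and fell by 0.57 in transduced cells, and Asns was higher by 0.36 and fell by 0.37. Erythroid genes had 3 of 9 members higher (adjusted p = 0.00747, and 0.0376 with an estimated correlation), and the transferrin receptor gene Tfrc fell by 0.37 in non-transduced cells and was higher by 0.29 in transduced cells. Adhesion molecules had 3 of 53 members higher and 8 lower (adjusted p = 0.0306), a call lost with an estimated correlation (adjusted p = 0.189).

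Transduced and non-transduced cells without doxycycline (Sox11-OFF against NT-OFF) differed in 1026 genes, 632 higher and 394 lower in Sox11-OFF, and in 3 genes by 2-fold or more. Aim1 was higher by 1.27 (SE 0.07, adjusted p = 1.82e-07), followed by Mars2 (0.89), Tmem107 (0.80), Ddx26b (0.71) and Paxbp1 (0.69). Tmem107 had a value of -0.055 when exon regions were averaged. Traj14 (-0.93), Slc39a3 (-0.90), Iglj3 (-0.88), Trap1a (-0.84) and Rln3 (-0.77) were lower. Ribosome biogenesis and MYC genes had 7 of 28 members higher and 0 lower, Gnl3 among them (0.40, SE 0.05), with a median of 0.08 and an adjusted p of 5.59e-04 that was 0.756 with an estimated correlation. In all 6 lists passed, and none held its call with an estimated correlation; 1 passed without Sox11-OFF replicate 2 and 3 without NT-OFF replicate 1. The count moved to 384 without Sox11-OFF replicate 2, 401 without Sox11-OFF replicate 3, 467 without NT-OFF replicate 3 and 540 without Sox11-OFF replicate 1, to 411 when only the 8 arrays of this comparison were fitted, to 563 with median centring and to 337 with the covariate. It was 1627 with trend and robust moderation, 1631 without dim genes and 2465 with the mean over exon regions. Cells and run cannot be told apart here.

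Transduced and non-transduced cells with doxycycline (Sox11-ON against NT-ON) differed in 9063 genes, 4564 higher and 4499 lower, and in 307 by 2-fold or more. Mmp8 (3.16, SE 0.14), Thsd1 (3.14), Aim1 (3.14), Gsta4 (2.58) and Tdrd12 (2.54) were higher (Mmp8, Thsd1 and Tdrd12 from levels below 7.30 in NT-ON), and C3ar1 (-3.33, SE 0.06), Ccl3 (-2.20), Cd68 (-2.11), Serpinb1a (-1.96) and Tarm1 (-1.94) were lower. Of 17 lists past the threshold, 3 held their call with an estimated correlation. The unfolded protein response had 17 of 21 members lower (median -0.29), erythroid genes 5 of 9 higher (median 0.26), and chemokines and migration receptors 9 of 33 lower and 1 higher (median -0.13) (adjusted p = 0.0388 with an estimated correlation in each case). G1/S genes had 29 of 32 members higher (median 0.54, adjusted p = 1.23e-19), with an adjusted p of 0.0657 with an estimated correlation. A constant difference between runs would show equally in Sox11-OFF against NT-OFF, where 1026 genes differed, 3 of them by 2-fold or more. It cancels in the difference of effects, which passed for 4821 genes, 210 of them by 2-fold or more. This argues against a constant run difference as the whole cause here. For genes that did not pass for the difference, cells and run cannot be told apart.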

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

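The tests of array quality, doxycycline by itself, granulocytes, neutrophils, scaling, leak and run difference, and the splits of non-transduced arrays alone for the difference of effects, were chosen after the results they bear on had been seen, and the other counts of splits of the arrays before.

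Doxycycline effects differed between transduced and non-transduced cells, by the limma test of the difference, for 4821 genes. The Sox11 region differed by 2.50. The differences were 3.57 for Mmp8, 2.58 for Tdrd12, 2.54 for S100a8, 2.52 for Thsd1, 2.51 for Gbp9, 2.33 for Glyat, 2.33 for Mpo, 2.31 for S100a9, 2.27 for Far2 and 2.22 for Zc4h2, all 10 from levels below the 95th percentile of the negative controls, 7.30. They were -2.96 for C3ar1, -2.09 for Serpinb1a, -2.02 for Ccl3, -1.92 for Tarm1, -1.90 for Cd68, -1.82 for Tmem154, -1.74 for Gapt, -1.73 for Ero1l, -1.63 for Casp4 and -1.61 for Tmem71.

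A single array stood apart from the other 3 of its group in 3 of 112 groups of values looked at, where chance gives about 5.6 (1 in 20). The median gene value was 5.85 on NT-ON replicate 1 and 5.78 to 5.79 on the others. Mmp8 was 9.42 on Sox11-ON replicate 2 and 9.18 to 9.22 on the others, and Tmem71 was 8.63 on Sox11-OFF replicate 4 and 8.77 to 8.79 on the others.

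Rows without a single gene symbol, 138904 exon regions and junctions that enter no gene value, also held a signal: 10845 of them passed in Sox11-ON against Sox11-OFF, and 10 in NT-ON against NT-OFF.

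The first pattern weighed is the large number of genes that changed with induction. Of the 35 splits of the 8 transduced arrays, 1, the real one, gave as many as 7863 genes, and the highest of the others gave 0. This argues against a chance division of these arrays. It cannot exclude a chance difference between cultures, since the 4 arrays of a group may not be separate cultures. The distance between positive and negative control probe sets was larger with doxycycline (mean ± SD, n = 4: 4.92 ± 0.04 in Sox11-ON, 4.81 ± 0.05 in Sox11-OFF, 4.98 ± 0.06 in NT-ON, 4.86 ± 0.02 in NT-OFF), and with it as a covariate 5667 genes passed, 4949 of them among the 7863. It did not overlap between Sox11-ON (lowest 4.89) and Sox11-OFF (highest 4.85), so this covariate cannot separate array quality from induction. The non-transduced groups differed in distance by a similar amount and gave 92 genes at the adjusted threshold. That argues against array quality, as measured by this distance, as the whole cause. Non-transduced cells gave 0.0117 times as many genes at the adjusted threshold, and 3991 against 10248 at an unadjusted limma p under 0.05. Of the 7863 genes, 4454 (56.6%) passed for the difference with the same sign, as did 260 of the 261 with a change of at least 2-fold. The difference includes the arrays on which these genes were called. This argues against doxycycline by itself as the whole cause, and leaves it open for genes that did not pass for the difference. Induction of the construct stays open as a hypothesis, and other differences between the Sox11-ON and Sox11-OFF samples were not tested.

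The second pattern is the rise of some granulocyte genes, such as Mmp8, S100a8 and Mpo, while Cd68 and Emr1 fell. Of 30 granulocyte genes listed for this test, which include genes already seen to rise and of which 16 were also on lists fixed beforehand, 29 were measured, 10 were higher and 3 lower (Itgam, at 9.76 in Sox11-ON after a change of -1.40, Tyrobp at 9.29 after -0.27, and Cebpe). The median log2 change was 0.10, with a 95% bootstrap interval of -0.03 to 0.81 on both sides of the limit of 0.5. The interval came from resampling the listed genes, not the arrays. It takes genes as independent and measures the spread within the list, so it decides nothing about the samples. Of the 15 mature neutrophil genes at a low level in Sox11-OFF, counted after that result, 8 had an upper 95% bound of change under 0.5, among them Lyz2, at 4.62 in Sox11-ON, and 7 were higher; but the 8 lie under the 95th percentile of the negative controls, 7.30, where probes that do not respond would look the same. Of 7 measured genes of immature granulocytes Mpo was higher (2.31) and Cebpe fell by 0.88 (SE 0.07), while Elane (-0.01), Prtn3 (-0.14), Ctsg (0.12), Ms4a3 (-0.16) and Fcnb (-0.09) did not pass, and of 4 eosinophil genes Epx was higher (1.73) and Prg2 (0.09), Prg3 (0.09) and Ear2 (0.13) did not pass. Scaling between arrays is argued against. It keeps the order of genes on an array, while all 10 higher genes ranked higher on every Sox11-ON than on every Sox11-OFF array (median shift 19.0 percentile points). The medians of genes of the transduced arrays differed by at most 0.118, against a median change of 1.73 of these 10 genes. Median centring, which took the genes lower with induction from 3795 to 2999, left that change at 1.75. With so small a range it could not have done otherwise, so it adds no support. A change within the cells and an admixture of granulocytes cannot be told apart.

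The third pattern is a shift of uninduced transduced cells toward the induced state. Of the 261 genes that changed at least 2-fold with induction, 171 (65.5%) had the same sign in Sox11-OFF against NT-OFF, with 37 of them called in the same and 9 in the opposite direction, although both comparisons share the Sox11-OFF arrays with opposite signs (covariance across genes 3.97e-05, against -0.00452 in simulated groups without effects). With those arrays split so that none served both comparisons, the same-sign share was over the limit of 60% in 5 of 6 splits, from 69.6% to 71.5% with Sox11-OFF replicate 4 on the induction side and from 58.2% to 63.1% without it there, and the covariance ran from 9.90e-04 to 0.00698. In simulated data, which take genes as independent and hold no run difference, the share ran from 50.2% to 55.2% without a leak and from 98.6% to 99.3% with a leak of 0.2 of the induction effect (median ratio of the 2 changes 0.00574 and 0.246), and the observed shares and ratios (0.0281 to 0.0964) lie between. The higher Sox11 region in Sox11-OFF goes with a leak of the construct, which may account for the shift, but the limit set for every split was missed in 1, and transduced and non-transduced arrays may differ by run, so the 2 cannot be told apart.

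For the other comparisons the counts from other splits of the arrays were as follows. In NT-ON against NT-OFF, 1 of 35 splits gave as many as 92 genes, the highest of the others 1. In Sox11-OFF against NT-OFF, 1 of 35 gave as many as 1026, the highest of the others 4. In Sox11-ON against NT-ON, 1 of 35 gave as many as 9063, the highest of the others 1. Each real grouping thus gave more genes than any other split, but the splits cannot exclude a chance difference between cultures. For the difference of effects 100 splits were drawn, and 2 gave as many as 4821, the real one included. The highest of the others gave 6114, and it was 1 of 3 drawn splits that kept the real groups of transduced arrays; the highest of the rest gave 1. With the transduced groups kept, 44 of all 70 splits of the non-transduced arrays gave as many (4333 to 6603 genes). The count thus rests on the grouping of the transduced arrays, with the same limit on cultures. The splits do not show that the real grouping of the non-transduced arrays adds to it.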

How the results depend on the processing

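The control distance covariate, the lists without single arrays and all settings of the overlap were chosen after the data had been seen. The numbers of genes changed in Sox11-ON against Sox11-OFF (7863), in the difference of effects (4821) and in Sox11-ON against NT-ON (9063) stayed within 1.5 times under both scalings, trend and robust moderation, array weights, the mean over exon regions, no dim genes, the replicate block, the covariate and without each array in turn. For Sox11-ON against Sox11-OFF they ran from 5667 (covariate) to 9537 (mean). They moved when each row was tested by itself, to 122656, 60614 and 172440 of many more rows, and with 2-fold as well, to 261, 210 and 307. NT-ON against NT-OFF (92) moved to 249 with trend and robust moderation, 4 with the arrays of the comparison alone, 323 without dim genes, 315 with the mean, 38 with median centring, 17 with the replicate block, 16 with the covariate, 166 by row, 0 with 2-fold as well, and 27 to 84 without single arrays. Sox11-OFF against NT-OFF (1026) moved in the same settings to 1627, 411, 1631, 2465 and 563, to 337 with the covariate, 30061 by row, 3 with 2-fold as well and 384 to 1017 without single arrays. The overlap, 48 genes changed by doxycycline in both kinds of cells, moved to 155, 4, 199, 187, 22, 13 and 9 in the order given for NT-ON against NT-OFF up to the covariate, and to 16 to 69 without single arrays. Dim genes left out means fewer genes tested, and a fit on 8 arrays has fewer residual degrees of freedom; for the other moves the cause was not tested. Of the lists, 14, 10, 16, 6 and 17 passed in the 5 comparisons; with an estimated correlation 5, 0, 7, 0 and 3 did. With fry 26 passed in Sox11-ON against Sox11-OFF, 6 in NT-ON against NT-OFF, 2 in Sox11-OFF against NT-OFF and 27 in Sox11-ON against NT-ON, and without dim genes 9 in Sox11-ON against Sox11-OFF. Without single arrays 1 to 7 lists passed in Sox11-OFF against NT-OFF. Sox11 with induction (0.04) was 0.13 with the mean over exon regions (adjusted p = 0.0184), 2.50 in region PSR1200010816 and -0.03 to 0.12 without single arrays. Reversed signs came from the mean over exon regions: Ccnd3 -0.010 with induction and -0.042 in Sox11-ON against NT-ON, Tmem107 -0.055, Fzd2 -0.023 and Rbpj -0.012 in Sox11-OFF against NT-OFF, and Stmn3 -0.0032 and Rbpj -0.17 in Sox11-ON against NT-ON; the cause was not tested. Of 8972 comparisons of 477 values of named genes 8555 kept direction and side of the threshold, 410 kept the direction alone and 7 reversed. As a pairing check, deviations from the group mean were correlated across genes between samples of the same number, with Pearson r from -0.22 to 0.30 (genes are not independent replicates), where pairs would all need r over 0.1. Of the 4 numbers 1 fitted its own best between Sox11-ON and Sox11-OFF and 0 between NT-ON and NT-OFF, but 3 between Sox11-OFF and NT-OFF (r 0.00 to 0.30), where the block gave 957 genes. The labels give the numbers no further meaning, and they were not taken to pair samples. Signal over background limits the values: 25.9% of genes had a mean below the median of the negative control probe sets.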

Other observations

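The families in this part were formed from the letters that open a gene symbol, after the data had been seen, and 255 families of at least 10 genes were tested with camera. Those described are a selection. With induction Hmgb (12 of 13 members higher, 0 lower, adjusted p = 8.36e-13) and Mcm (7 of 10 higher, 0 lower, adjusted p = 1.61e-07) passed as well. Both lost their call with an estimated correlation (adjusted p = 0.197 and 0.346). Most Hmgb members that rose bear symbols of Hmgb1 pseudogenes or related sequences, with close values (such as Hmgb1-ps6 at 0.62 and Hmgb1-ps4 at 0.71). Their probes can share sequence, so these members are not independent. Of the other genes, Hmgb3 was higher by 1.23 and Hmgb2 by 0.23, and Hmgb4 did not pass (-0.11). Clustered protocadherin beta genes, which encode homophilic adhesion molecules of neurons, had 8 of 21 members higher with induction and 0 lower (median log2 change 0.10, adjusted p = 4.95e-04, and 0.0948 with an estimated correlation). Pcdhb17 was higher by 1.75 (SE 0.07), Pcdhb16 by 1.58 (SE 0.16) and Pcdhb19 by 1.27 (SE 0.13). Guanylate-binding protein genes had 7 of 11 members higher and 0 lower (median 0.44, adjusted p = 1.55e-04, and 0.0948 with an estimated correlation), with Gbp4 at 1.14 and Gbp8 at 1.02 beside Gbp9. They also passed with doxycycline in non-transduced cells, with 1 higher (median 0.14, adjusted p = 0.00249, and 0.461 with an estimated correlation), and did not pass for the difference of effects, with 4 higher (median 0.38, adjusted p = 0.0538). Histone genes had 17 of 35 members higher and 3 lower (adjusted p = 2.08e-04, and 0.197 with an estimated correlation), with Hist1h2bh at 1.13 and the linker histone gene Hist1h1c at -1.18. In non-transduced cells the protocadherin and histone families did not pass (adjusted p = 0.820 and 0.878), and for the difference of effects they did (0.00137 and 5.41e-04, and 0.191 and 0.366 with an estimated correlation). The medians of these families kept their sign under quantile normalization and median centring.

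None of the families that follow held its call with an estimated correlation. Of 11 genes whose symbols begin with Srsf, which encode splicing factors, 7 were higher and 0 lower (adjusted p = 1.91e-05, and 0.264 with an estimated correlation), with Srsf7 at 0.74 and Srsf1 at 0.73. Of 14 regulatory proteasome subunit genes (Psmd) 11 were higher and 1 lower (adjusted p = 4.58e-06, and 0.349 with an estimated correlation). In non-transduced cells Srsf and Psmd genes did not pass (adjusted p = 0.930 and 0.479), and for the difference of effects they did (9.43e-06 and 8.95e-05). Of symbols that begin with Rpl 99 of 157 were lower, and of those with Rps 59 of 98 (adjusted p = 3.27e-17 and 3.53e-12, and 0.428 for both with an estimated correlation). Symbols that end in ps, the usual mark of pseudogenes, carried these counts, with 89 of 130 Rpl and 52 of 64 Rps symbols lower. Of the other symbols 10 of 27 Rpl were lower and 2 higher, and 7 of 34 Rps were lower and 3 higher. Probes of pseudogenes can share sequence with the functional genes, so members are not independent.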
